A study of Mus musculus with 39 samples.

How the data were processed

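Gene expression in mouse parathyroid glands was measured by RNA sequencing in 39 samples, 21 from Bmal1 flox/flox control mice (WT) and 18 from littermates that also carried a parathyroid Cre transgene (KO). Per the labels' protocols, each sample pooled the glands of 2 male mice, total RNA was used, and libraries were made with a stranded, ribosomal RNA depleting kit. Times were taken from the sample titles, as ZT 0, 4, 8, 12, 16 and 20. For 3 samples titled ZT16 (WT replicates 4 and 5 and KO replicate 1) another label gave ZT 20; they were grouped by title, and both other treatments were run as alternatives.

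The authors deposited raw gene counts, whole numbers per gene and sample. The submitters' processing notes name STAR 2.7.8a, featureCounts 2.0.1, DESeq2 1.30.1 and build mm10, without saying which step each served. The annotation and the strand setting of the counting are not given in the sources used here, so genes that overlap on opposite strands may share reads. Of the counts from 1 to 10, 89.6% were even, as when both mates of a read pair are counted, so the depth in fragments is near the counts divided by 2. Libraries held 38111766 to 68938704 counts. The table had 27179 gene IDs, of which 25275, with 98.0% of the counts, matched the reference gene table of assembly GRCm38.p6, used for symbols and coordinates. Counts were turned into CPM with trimmed mean of M-values (TMM) factors, which ranged from 0.837 to 1.08. They were below 1 in most WT libraries and above 1 in most KO libraries.

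Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood fit, robust, TMM, low counts filtered by group with filterByExpr), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The genotype effect was fitted over all 39 samples with time as a factor of 6 levels. Rhythms were tested as 2 cosine terms of a 24 h period within each genotype, and the difference in rhythm as 2 interaction terms over all samples. Amplitudes (from the mean to the peak, on the log2 scale) and peak times, with SE, came from a least squares cosine on log2 CPM with a prior count of 2. Across alternatives the amplitudes of edgeR's own fit were compared, which differ slightly from these. Clock genes were also compared at each time within a fit of 12 group means.

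The 28 gene lists, 449 entries of which 448 matched, covered core clock genes with E-boxes and with ROR elements, clock output, glucocorticoid response, heat shock, cold-inducible, immediate early, parathyroid identity, secretory pathway, Pth mRNA binding, endoplasmic reticulum folding, proliferation, cell cycle regulators, oxidative phosphorylation, glycolysis, ribosomal protein and interferon genes. They also held markers of thyroid follicles, C cells, lymphoid tissue, skeletal muscle, fat, blood, macrophages, endothelium, fibroblasts, nerve and airway. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation, and with fry. Marker scores (mean log2 CPM of a list) were compared by two-sided permutation with 100000 resamples. The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined.

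Named genes were Arntl, all clock genes, the 8 largest rises and 8 largest falls by genotype and the 8 largest amplitudes in each genotype among genes past the threshold with a mean of at least 1 CPM, up to 8 genes with a different rhythm, and up to 4 genes of smallest p from each other list. For the lists of clock output, cell cycle, parathyroid identity and secretion, up to 4 genes of smallest p for rhythm in WT were added. Results of 1 gene are not reported here. Gene models without a proper symbol, pseudogenes and genes not coding for protein were passed over in the ranked parts.

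On simulated counts with 200 genes changed among 18661, the genotype test recovered 59.0% of changes of 0.5 and 79.0% of changes of 1 on the log2 scale, and the cosine test recovered 62.0% and 71.0% of such amplitudes at the WT numbers and 56.0% and 76.0% at the KO numbers. The interaction test recovered 46.0% and 67.0%. False calls were 6 of 144 for genotype, 12 of 145 for rhythm in WT, 10 of 142 for rhythm in KO and 10 of 123 for the interaction. The simulated genes varied independently, without shared variation such as tissue content, so recovery in these libraries may differ. Replicates within groups were compared by chi-square over genes: the 48 pairs differed by 39.1 to 407 per gene, far above sampling noise, so no 2 replicates were copies of one library.

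Alternatives were DESeq2 1.42.0 as the test, its size factors in edgeR, no low-count filter and a filter at a mean of 1 CPM. Further fits had no time term or a cosine time term, and time as a factor for rhythms. Covariates were the thyroid score, 4 tissue scores (thyroid, lymphoid, muscle, fat), the replicate number as a block, or the number in the titles. Equal numbers of samples were also drawn, and each sample was left out in turn. CPM without TMM was run for the marker scores alone. No test of genes, rhythms or lists was run without TMM or size factors. Added after the data were seen were halved counts, leaving out WT ZT0 replicate 1 and WT ZT16 replicate 1, which differed from the rest in composition, and leaving out 12 libraries with a lymphoid score above 1, among them both KO samples of ZT12. Figures were drawn with matplotlib 3.10.9.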

Results

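RNA was sequenced from mouse parathyroid glands, the endocrine glands that secrete parathyroid hormone, at 6 times of day 4 h apart from lights on (zeitgeber time, ZT, 0). The mice had both copies of Bmal1 (gene symbol Arntl), a core transcription factor of the circadian clock, flanked by loxP sites around exon 8. Control littermates carried no Cre recombinase (21 samples, called WT), and knockout mice carried Cre under a human parathyroid hormone promoter (18 samples, called KO). WT samples numbered 3 at ZT0, 4 at ZT4, 2 at ZT8, 3 at ZT12, 5 at ZT16 and 4 at ZT20, and KO samples numbered 3, 3, 3, 2, 3 and 4 at the same times. Each sample held glands pooled from 2 male mice, so the p-values of single genes, of fry and of marker scores measure the spread between such pools. Camera at a preset correlation and the tests by position on chromosomes compare genes with other genes. The libraries held 38111766 to 68938704 counts (median 55836787), with 16883 to 20184 genes detected. Parathyroid hormone (Pth) took 6.34 to 19.1% of a library's counts (median 11.5%) and the secretory granule gene Chga took 7.77 to 13.7%. Thyroglobulin (Tg), a thyroid follicle gene, ranged from 0.537 to 63010 CPM (counts scaled to the library size) between libraries.

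The targeted gene, Arntl (Entrez ID 11865, mm10 chromosome 7, 113178471 to 113314126), was read in every sample. Its WT levels were 39.7, 40.1 and 41.9 CPM at ZT0, 34.4, 27.1, 26.9 and 26.9 at ZT4, 14.1 and 9.98 at ZT8, and 4.47, 2.09 and 2.64 at ZT12. At ZT16 the WT samples held 7.96, 32.3, 24.5, 27.2 and 14.3 CPM, and at ZT20 they held 27.6, 23.4, 22.0 and 23.7 CPM. KO levels were 20.1, 25.4 and 31.3 CPM at ZT0, 20.6, 19.1 and 18.9 at ZT4, 11.6, 13.0 and 11.5 at ZT8, and 12.6 and 8.21 at ZT12. They were 7.93, 12.3 and 12.0 CPM at ZT16, and 16.6, 20.4, 17.5 and 23.6 CPM at ZT20. Over all times Arntl averaged 22.5 ± 12.2 CPM in WT (SD, n = 21) and 16.8 ± 6.24 CPM in KO (SD, n = 18), a log2 fold change of -0.25 ± 0.19 (SE; adjusted p = 0.465), which did not pass the test. Over 15 alternatives that fold change ranged from -0.466 (without 12 lymphoid-rich libraries) to -0.175 (without the 3 samples of unclear time) and passed in 0 (lowest adjusted p = 0.189). Within times, Arntl was higher in KO at ZT12 (log2 fold change 1.76 ± 0.35, adjusted p = 1.15e-04) and lower at ZT16 (-0.99 ± 0.28, adjusted p = 0.00546), each adjusted over the clock genes and times. These gene-level counts include the exons outside the deletion, so they check the genotype labels little. Reads from other tissue in the libraries were counted as well, and their share was not measured.

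KO glands had more mRNA of Npas2, a relative of Clock that pairs with BMAL1, which averaged 2.14 ± 1.99 CPM in WT and 12.1 ± 3.49 CPM in KO (SD; log2 fold change 2.87 ± 0.25, adjusted p = 7.78e-10). The adrenergic receptor gene Adra2c rose from 0.335 to 2.7 CPM (3.02 ± 0.18, adjusted p = 1.66e-14). The sphingosine-1-phosphate receptor genes S1pr1, from 7.98 to 26.1 CPM (1.75 ± 0.12, adjusted p = 2.43e-12), and S1pr5 (2.02 ± 0.25) rose as well. The glycosyltransferase gene Gcnt4 rose from 4.91 to 20.1 CPM (2.11 ± 0.34, adjusted p = 6.48e-05). Galntl6, another glycosyltransferase gene, fell from 8.33 to 1.96 CPM (-1.96 ± 0.29, adjusted p = 1.42e-05).

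Between genotypes 1435 of 18661 genes tested passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 668 higher and 767 lower in KO (n = 21 and 18), with time of day as a factor. Most differences were small: the median absolute log2 fold change of the 1435 was 0.303, and 174 genes changed at least 2-fold, 108 up and 66 down. Among the 8 largest rises were also H2-Q1, a class I histocompatibility gene (3.47 ± 0.54), Hmga1b (2.09 ± 0.49) and Raet1e (1.89 ± 0.45). The largest falls were also of Trim12a, the kallikrein genes Klk1b22 (-3.44 ± 0.43) and Klk1b9 (-1.60 ± 0.35), the cystatin gene Cst12 (-1.93 ± 0.24), Gdpd3 (-1.91 ± 0.34), the secreted Wnt inhibitor gene Sfrp5 (-1.78 ± 0.50) and the nicotinic receptor subunit gene Chrna1 (-1.70 ± 0.29). Trim12a had 5658 counts over the WT libraries (2.68 to 10.0 CPM in each) and 2 counts, both in 1 library, over the KO libraries, a ratio of 2474 with a 95% exact binomial interval of 444.3 to 97890, computed on halved counts (2833 and 1) since both mates seem to be counted; it covers counting error only. Trim12a, H2-Q1, Raet1e, Hmga1b and the Klk1b genes have near-identical relatives, so their counts depend on how shared reads were assigned and their values are uncertain. Markers of lymphoid tissue varied widely between libraries: without the 12 libraries of highest lymphoid score (6 of each genotype) 454 genes passed, 237 higher and 217 lower, while with scores of 4 tissues (thyroid, lymphoid, muscle and fat) as covariates 2158 passed (1119 higher, 1039 lower). Both KO samples of ZT12 are among those 12 libraries, so fits without them hold no KO sample at ZT12. Klk1b9, Sfrp5 and Arntl2 did not pass without those 12 libraries, nor did many genes of the lists below. With fewer samples tested there, the log2 fold changes of Klk1b9 (-1.47) and Sfrp5 (-1.86) stayed about as large, and that of Arntl2 shrank to 0.21.

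Within the clock, the genes under control of ROR elements, which the repressor REV-ERB turns down, were higher in KO. Of the 8 such genes measured, 5 rose, among them Npas2, Cry1, Nfil3 and Arntl2, and 0 fell. The repressor gene Cry1 rose from 33.6 ± 13.6 to 75.1 ± 9.92 CPM (SD; log2 fold change 1.3 ± 0.12, adjusted p = 1.21e-09) and the transcription factor gene Nfil3 from 3.59 ± 2.02 to 6.83 ± 1.93 CPM (1.22 ± 0.20, adjusted p = 5.00e-05). Arntl2 was 0.39 ± 0.10 higher (adjusted p = 0.0150), and Arntl, Clock and Rora did not pass. Of the 12 clock genes driven through E-boxes, the sites that BMAL1 binds, Cry2 (0.52 ± 0.08, adjusted p = 1.67e-05) and Per2 (0.62 ± 0.14, adjusted p = 0.00303) rose, and the REV-ERB gene Nr1d2 fell from 102 ± 67.4 to 52.5 ± 32.3 CPM (-0.85 ± 0.13, adjusted p = 4.64e-05). Nr1d1 (-0.39 ± 0.14, adjusted p = 0.0799), Tef (0.30 ± 0.10, adjusted p = 0.0578) and Dbp (-0.12 ± 0.16, adjusted p = 0.708) did not pass over all times by edgeR. Of 15 alternatives, Tef passed in 4, Nr1d1 in 2 and Dbp in 0, with DESeq2 among those for Tef and Nr1d1.

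Adjusted over all genes 8 of the 20 clock genes passed by genotype, and adjusted over the list alone 12 did. Per2 did not pass in a fit with no term for time (adjusted p = 0.450). The clock lists were fixed before the data were examined.

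At single times of day, 41 of 120 contrasts over the 20 clock genes passed, 30 higher and 11 lower in KO, in 14 genes. Cry1 and Npas2 were higher in KO at all 6 times, most at ZT8 for Cry1 (log2 fold change 2.32 ± 0.16, adjusted p = 1.22e-13) and at ZT12 for Npas2 (4.64 ± 0.54, adjusted p = 1.66e-08). Nfil3 was higher at ZT4, ZT8, ZT12 and ZT20, with 2.78 ± 0.39 at ZT8. In the hours after lights on, Per2 (1.24 ± 0.29 at ZT0), Cry2 (0.92 ± 0.16), Tef (1.14 ± 0.16) and Bhlhe41 (0.89 ± 0.24) were higher in KO at ZT0 and again at ZT4. At ZT8 the daytime genes Nr1d1 (-1.27 ± 0.28), Nr1d2 (-1.36 ± 0.33), Dbp (-1.36 ± 0.31) and Bhlhe40 (-1.15 ± 0.30) were lower in KO. Nr1d1, Nr1d2, Dbp and Per3 were also lower at ZT12, Nr1d2 at ZT4 and ZT20, and Tef was higher at ZT16. At ZT12 genotype went with tissue content: the lymphoid marker score (mean log2 CPM) was 1.51 and 2.36 in the KO samples and -1.86, -3.06 and -1.86 in the WT samples. Values were edgeR contrasts within each time from a shared fit of 12 groups, adjusted over the 120 contrasts alone. With 2 WT samples at ZT8 and 2 KO samples at ZT12, the test at these times assumes that they vary like the other groups.

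**Figure D1:**
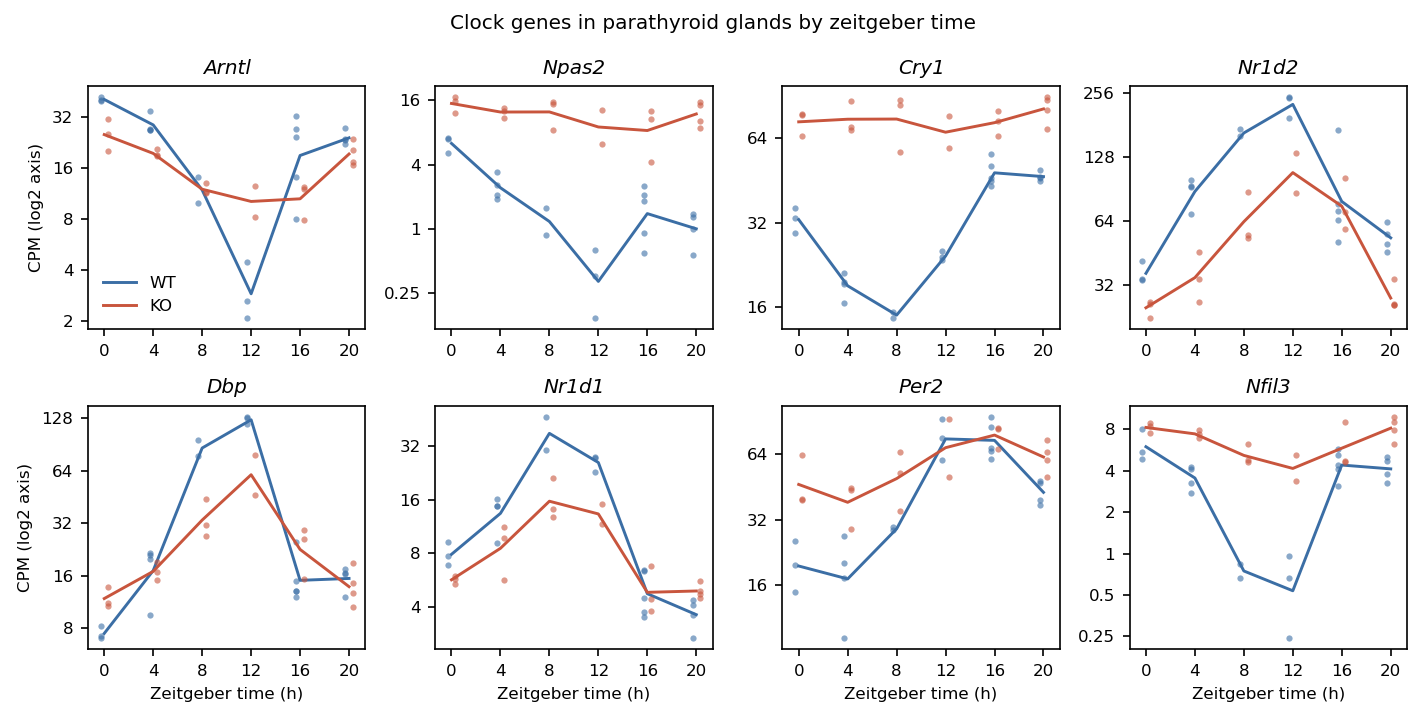
Expression of clock genes in CPM (vertical log2 axis) against zeitgeber time in hours (horizontal axis) in WT and KO. Each point is 1 sample pooled from 2 mice and lines join the geometric means of the groups (n = 2 to 5); Cry1 and Npas2 lie higher in KO at all 6 times, while the Arntl lines cross between ZT4 and ZT8 and again between ZT12 and ZT16.

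In WT glands 11 of the 20 clock genes cycled over 24 h. Dbp, a clock-driven transcription factor gene, had the largest amplitude among genes past the test with a mean of at least 1 CPM, 1.79 ± 0.26 on the log2 scale (SE, n = 21; peak to trough 11.9-fold) with its peak at ZT 10.3 (adjusted p = 9.28e-04), and Nr1d1 peaked at ZT 8.09 with an amplitude of 1.64 ± 0.16 (adjusted p = 4.94e-06). Nr1d2, Per3 and Per2 followed at ZT 10.2, 11.8 and 14.6 with amplitudes of 1.22 ± 0.14, 1.09 ± 0.13 and 1.17 ± 0.11. Cry1 peaked at ZT 18.8 (0.86 ± 0.05, adjusted p = 6.48e-10). Outside the clock lists, Col5a3, a collagen gene, peaked at ZT 1.2 (1.29 ± 0.17, adjusted p = 6.87e-04) and Pnpla3, a lipid hydrolase gene, at ZT 23.3 (0.98 ± 0.16, adjusted p = 0.00619). The clock output genes Wee1, a cell cycle kinase gene (0.36 ± 0.06, peak ZT 13.8, adjusted p = 0.00887), Usp2 (0.51 ± 0.11, peak ZT 12.0) and Tsc22d3 (0.26 ± 0.05, peak ZT 13.7) also passed, as did Fkbp5, a glucocorticoid-induced gene (peak to trough 3.80-fold, peak ZT 13.1, adjusted p = 0.00264), which was picked out after its values were seen.

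A 24 h cosine was past edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment for 45 of 18131 genes in WT, 34 of them outside the clock lists. Adjusted over the list alone, 17 of the 20 clock genes passed in WT. Without WT ZT12 replicate 3 the count of genes was 27, and without the lymphoid-rich libraries it was 25. Without 2 libraries of unusual composition it was 23, and with 17 samples of each genotype it was 21 (median of 20 draws, 10 in KO). Wee1 and Tsc22d3 passed in neither of the 2 fits without libraries of unusual or lymphoid-rich composition (highest adjusted p of Wee1 0.0696), and Usp2 did not pass without the 2 libraries. With the replicate block neither Usp2 nor Tsc22d3 passed. Usp2 was also lost with the title number as a covariate and Tsc22d3 with time as a factor. Over the alternatives, some with fewer samples, their amplitudes ranged from 0.36 to 0.46 for Wee1, 0.22 to 0.30 for Tsc22d3 and 0.48 to 0.68 for Usp2. Per1 (adjusted p = 0.0499) passed in 5 of the 21 fits that left out 1 library, Tsc22d3 in 9 and Usp2 in 13. DESeq2 called 342 genes rhythmic in WT.

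In KO glands Nr1d2, Dbp, Per3 and Nr1d1 still cycled, with amplitudes of 1.09 ± 0.12, 1.04 ± 0.13, 0.88 ± 0.10 and 0.87 ± 0.12 on the log2 scale (SE, n = 18; adjusted p = 6.31e-04, 0.00111, 5.97e-04 and 0.00173). Their peaks lay at ZT 11.9, 11.1, 13.3 and 8.42. Cre was under a parathyroid hormone promoter and the libraries also held other tissue, such as thyroid. Which cells these KO rhythms came from was not tested. Arntl cycled in KO with an amplitude of 0.72 ± 0.09 and a peak at ZT 0.283 (adjusted p = 0.00111), and in WT its fitted amplitude was 1.49 ± 0.26 with a peak at ZT 23.4 (adjusted p = 0.109). The WT rhythm of Arntl passed by DESeq2 and with time as a factor (adjusted p from 0.00251 to 0.269 over the alternatives), and the difference in its rhythm between genotypes did not pass (adjusted p = 1.00). Among genes past the test with a mean of at least 1 CPM, Col5a3 had the largest KO amplitude (1.44 ± 0.20, peak ZT 1.10, adjusted p = 0.00367). The elastin gene Eln (0.88 ± 0.16, adjusted p = 0.0443) and the cold-inducible RNA binding gene Rbm3 (0.63 ± 0.11, peak ZT 6.44, adjusted p = 0.0331) passed as well.

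In KO 14 of 17969 genes passed the cosine test, 8 of them outside the clock lists; 6 of the 20 clock genes passed, and 12 adjusted over the list alone. Of the genes rhythmic in WT and in KO, 7 were shared (Nr1d1, Nr1d2, Tef, Serinc3, Per3, Dbp and Col5a3), where independent lists would share 0.0357, and the peaks of all 7 lay within 2 h of each other. The KO count was the least stable. With the 4 tissue scores it was 1, and without the lymphoid-rich libraries, which include both KO samples of ZT12, it was 2. Without KO ZT4 replicate 3 it was 7, without KO ZT12 replicate 1 it was 8 and without KO ZT8 replicate 1 or KO ZT16 replicate 1 it was 9. Eln passed in 4, Tef in 6 and Rbm3 in 8 of the 18 fits that left out 1 library, and in 6, 7 and 10 of 14 alternatives. These genes were lost with the 4 tissue scores and with the replicate block, and Eln and Tef also without the lymphoid-rich libraries. Arntl, Nr1d2, Dbp, Col5a3 and Per3 (adjusted p = 0.298) did not pass without the lymphoid-rich libraries. With the 4 tissue scores Arntl, Nr1d2, Dbp, Nr1d1 and Col5a3 did not pass. For Per3 the KO amplitude in edgeR's fit over the alternatives ranged from 0.79 to 0.93, and for the latter 5 genes from 0.64 to 0.71, 0.95 to 1.11, 0.80 to 1.2, 0.74 to 0.90 and 1.36 to 1.66. DESeq2 called 85 genes rhythmic in KO.

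The rhythm itself differed between genotypes for Cry1. The Cry1 amplitude was 0.86 ± 0.05 in WT and 0.07 ± 0.07 in KO (adjusted p of the difference = 2.42e-08). Smaller fitted amplitudes in KO were the rule in the clock: 18 of the 20 genes had one, among them Nr1d1 (1.64 ± 0.16 in WT, 0.87 ± 0.12 in KO), Dbp (1.79 ± 0.26 and 1.04 ± 0.13), Per2 (1.17 ± 0.11 and 0.49 ± 0.11) and Nfil3 (1.58 ± 0.26 and 0.49 ± 0.10), while Hlf (0.71 ± 0.25 and 0.82 ± 0.16) and Arntl2 did not. Outside the clock they were also common, in 30 of 31 proliferation, 28 of 39 oxidative phosphorylation and 23 of 31 ribosomal protein genes. Heat shock (4 of 15) and macrophage genes (4 of 12) were among the lists that went the other way. The count of 18 alone is thus not particular to the clock. Pth and the parathyroid transcription factor genes were not among the genes with a different rhythm.

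Genotype by time interaction terms in edgeR passed for 3 of 18661 genes, among them Cry1 and the immunoglobulin segment Igkv3-12, at a mean of 0.0956 CPM. Adjusted over the list alone, the rhythm differed for 11 of the 20 clock genes. For Dbp, Nr1d2 and Per3 the adjusted p of the difference over all genes was 1.00. Over the 20 clock genes alone it was 0.0415 for Dbp, 0.0406 for Per3 and 0.0506 for Nr1d2. A gene that passed in WT and not in KO is not thereby shown to have lost its rhythm. For Per2, 1 such gene, the adjusted p of the difference was 0.509 over all genes and 0.00213 over the 20 clock genes alone.

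**Figure D2:**
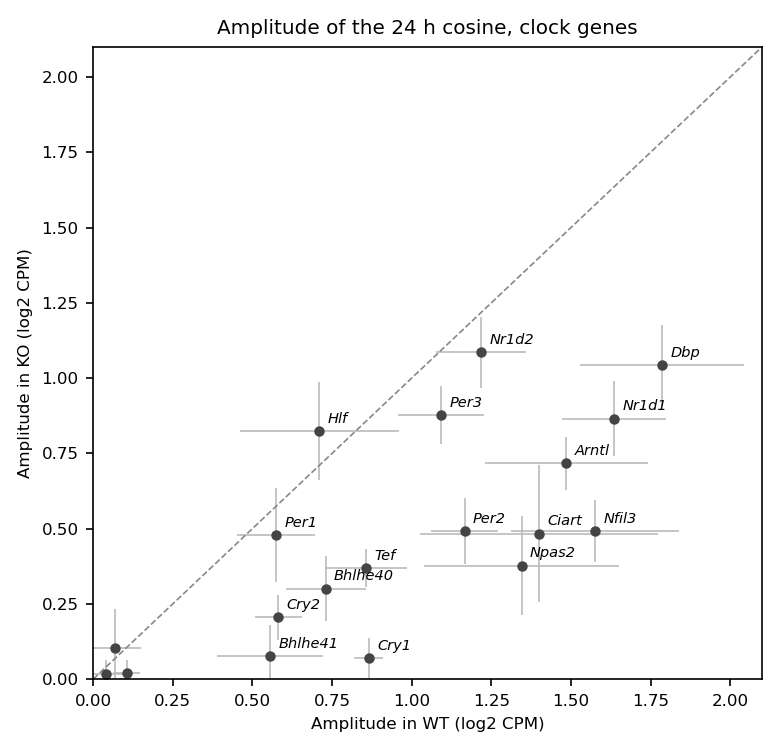
Fitted 24 h amplitude on the log2 scale of clock genes in WT (horizontal axis) and KO (vertical axis). Each point is 1 gene, bars are SE and the dashed line marks equal amplitudes; most genes lie below it, and Cry1 (0.86 in WT, 0.07 in KO) is among the farthest.

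Genes of oxidative phosphorylation, the mitochondrial chain that makes ATP, were slightly lower in KO. Fold changes in this paragraph are after TMM scaling, with a median log2 fold change of 0.000977 over all tested genes. The oxidative phosphorylation list did not pass camera with an estimated correlation (adjusted p = 0.693). Of 39 measured, 15 fell, 0 rose and 38 had a negative log2 fold change (median -0.14); Ndufa1 (-0.31 ± 0.06, adjusted p = 1.86e-04), Cox7c (-0.24 ± 0.06), Atp5o (-0.19 ± 0.05) and Uqcrc1 (-0.15 ± 0.03) were among those that fell. Of 21 genes for protein folding in the endoplasmic reticulum, 9 fell and 0 rose (median -0.22), with Sdf2l1 (-0.45 ± 0.10, adjusted p = 0.00354), Pdia6 (-0.29 ± 0.06), Pdia4 (-0.29 ± 0.08) and the chaperone gene Calr (-0.24 ± 0.07) as examples. Of 15 heat shock genes 3 fell: Hspa8, from 1068 to 777 CPM (-0.42 ± 0.09, adjusted p = 0.00253), Hspb1 (-0.34 ± 0.06) and Hspa4l (-0.20 ± 0.05). Of 18 glycolysis genes 4 fell, Hk2 (-0.69 ± 0.18, adjusted p = 0.0122), Gapdh (-0.20 ± 0.05), Pgk1 (-0.19 ± 0.04) and Gpi1 (-0.17 ± 0.04), and of 31 ribosomal protein genes Rps2 (-0.33 ± 0.06) and Rps18 (-0.22 ± 0.07) fell while Rpl30 (0.37 ± 0.07) and Rpl3 (0.17 ± 0.05) rose. Of the genes named in this paragraph, Ndufa1, Uqcrc1, Hspb1, Rps2 and Rpl30 passed without the 12 lymphoid-rich libraries and the others did not. With fewer samples tested there, log2 fold changes stayed close to those above, as for Gapdh (-0.18), Pgk1 (-0.19), Cox7c (-0.21), Pdia6 (-0.26) and Pdia4 (-0.23). Rps18 also lost its call in 14 of the 39 fits that left out 1 library and with the 3 samples of unclear time left out. Calr and Pdia4 lost theirs without WT ZT8 replicate 1, and Calr also with no time term.

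Of 28 lists, 7 passed camera with a preset correlation of 0.01. The list of ROR element clock genes was higher (median 0.66, adjusted p = 2.66e-13), and was the only one of the 7 that held with an estimated correlation (adjusted p = 3.02e-04). The lists that were lower lost the call with an estimated correlation: oxidative phosphorylation (adjusted p = 2.62e-14, and adjusted p = 0.693 with an estimated correlation), endoplasmic reticulum folding (3.38e-07 and adjusted p = 0.693 with an estimated correlation), and heat shock (7.48e-04), ribosomal protein (9.04e-04) and glycolysis genes (0.0172), each with adjusted p = 0.861 with an estimated correlation. The lymphoid marker list was higher (median 1.00, adjusted p = 0.0477, and adjusted p = 0.861 with an estimated correlation), with 0 of its 16 genes past the test, and passed in 16 of the 39 fits that left out 1 library. It did not pass with the 4 tissue scores (adjusted p = 0.699), with genes of at least 1 CPM alone (adjusted p = 0.126), with halved counts (adjusted p = 0.0975), with DESeq2 size factors (adjusted p = 0.0542) or without 2 libraries of unusual composition (adjusted p = 0.0944). Without the lymphoid-rich libraries it was higher in KO (adjusted p = 1.5e-06, but 0.583 with an estimated correlation), which decides nothing, since those libraries were chosen by the score of these same genes. Adjusted over the list alone, 30 oxidative phosphorylation genes, 15 folding genes, 5 heat shock genes and 4 glycolysis genes fell, and 3 ribosomal protein genes fell and 2 rose. By fry, which asks whether a list moves one way on balance, ROR element clock genes (adjusted p = 2.59e-09), oxidative phosphorylation (adjusted p = 0.0216) and folding genes (adjusted p = 0.0380) passed. The folding list did not pass fry without the lymphoid-rich libraries (adjusted p = 0.302) or with halved counts (adjusted p = 0.0536), nor did oxidative phosphorylation without those libraries (adjusted p = 0.179). When genotype was reassigned at random within times, 81 of 100 assignments, the real one included, gave 7 or more such lists. Without the 12 lymphoid-rich libraries, 2 oxidative phosphorylation, 1 folding, 1 heat shock and 0 glycolysis genes fell (17, 10, 5 and 4 with an unadjusted p under 0.05), 1 ribosomal protein gene fell and 1 rose, and the ribosomal protein list did not pass camera (adjusted p = 0.0717). The glycolysis list did not pass camera without KO ZT20 replicate 4 (adjusted p = 0.0580), with the 4 tissue scores (adjusted p = 0.0593) or with genes of at least 1 CPM alone (adjusted p = 0.0568).

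**Figure D3:**
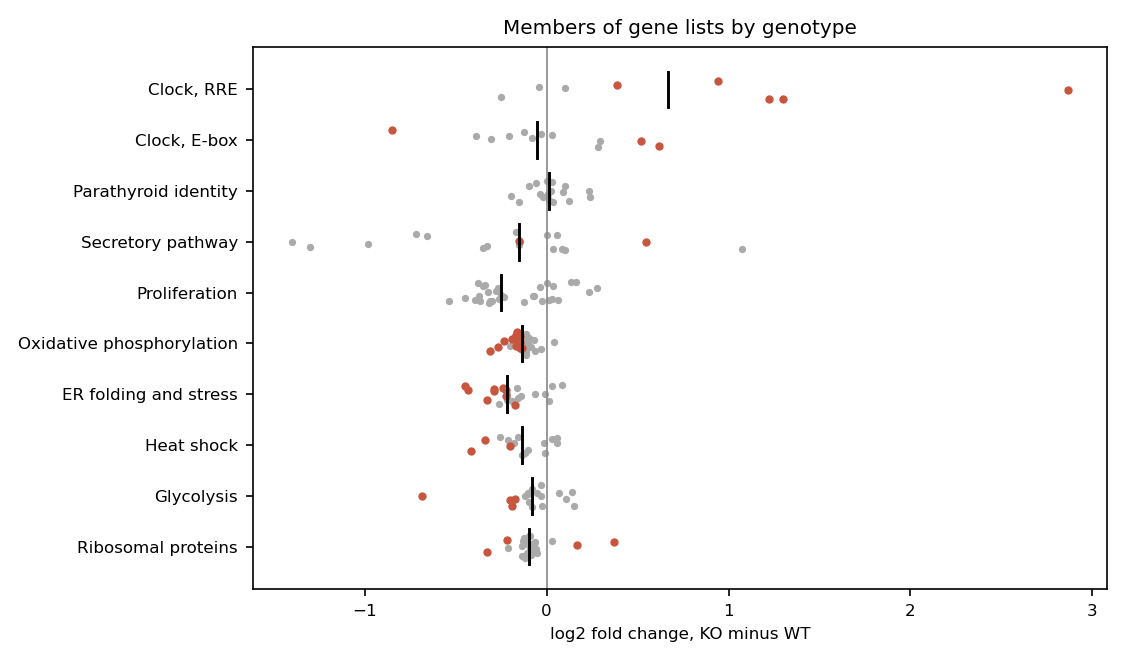
Log2 fold change of KO over WT (horizontal axis) for the members of the gene lists (vertical axis). Each point is 1 gene, red points passed the test over all genes and the black bar is the list's median; the oxidative phosphorylation genes lie close together around -0.14, with 38 of 39 below 0.

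Genes that mark the parathyroid cell differed little between genotypes. Pth itself averaged 121800 CPM in WT and 105600 CPM in KO (log2 fold change -0.20 ± 0.12, adjusted p = 0.357), the calcium-sensing receptor gene Casr 2737 and 2954 CPM (0.12 ± 0.06, adjusted p = 0.281), and the parathyroid transcription factor gene Gcm2 400.5 and 381 CPM (-0.06 ± 0.06, adjusted p = 0.650). The vitamin D receptor gene Vdr was 0.24 ± 0.08 higher (adjusted p = 0.0693) and Gata3 0.23 ± 0.09 higher (adjusted p = 0.124), neither past the test. Vdr passed in 6 of 15 alternatives, the 4 tissue scores and DESeq2 among them (adjusted p from 0.00726 to 0.310), and Gata3 in 2 of 15 (0.0389 to 0.670). Of 17 parathyroid identity genes 0 passed by edgeR (median 0.02, list adjusted p = 0.621), 3 had an unadjusted p under 0.05 and DESeq2 called 1. None of the 17 was rhythmic by edgeR in WT (3 unadjusted) or KO (2 unadjusted), and DESeq2 called 0 in either, with Casr at an amplitude of 0.19 ± 0.07 in WT (adjusted p = 0.333).

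Among 18 genes of the secretory pathway, Sytl4, which encodes a granule docking protein, rose from 542 to 802 CPM (0.54 ± 0.09, adjusted p = 1.55e-04) and Rab27a fell (-0.15 ± 0.05, adjusted p = 0.0464), a call kept in 10 of the 39 fits that left out 1 library. The list did not pass (adjusted p = 0.660). Of 20 clock output genes Leo1 rose (0.23 ± 0.05) and Nampt (-0.20 ± 0.05), Fmo2 (-0.49 ± 0.14) and Coq10b (-0.26 ± 0.07) fell, with a list adjusted p of 0.415. Nampt and Coq10b lost the edgeR call without WT ZT8 replicate 1 (adjusted p = 0.0537 and 0.0640), and Fmo2 lost it with no time term. Without the lymphoid-rich libraries 0 of the 20 passed (5 unadjusted, by edgeR), with fewer samples and log2 fold changes about as large: 0.23 for Leo1, -0.19 for Nampt, -0.42 for Fmo2 and -0.31 for Coq10b. Of 16 glucocorticoid response genes Fkbp5 (-0.53 ± 0.15, adjusted p = 0.0242) and Ddit4 (-0.26 ± 0.07, adjusted p = 0.0283) fell, with a list adjusted p of 0.262. Neither passed with no time term or without the lymphoid-rich libraries, where 0 of the 16 passed (2 unadjusted, by edgeR), and each lost the call without KO ZT16 replicate 2 (also Fkbp5 without WT ZT8 replicate 1, and Ddit4 without WT ZT12 replicate 3). Their log2 fold changes over the alternatives ranged from -0.67 to -0.46 for Fkbp5 and from -0.29 to -0.22 for Ddit4. Of 28 cell cycle regulators, the phosphatase gene Cdc25b fell (-0.61 ± 0.15, adjusted p = 0.00999; list adjusted p = 0.415), and adjusted over the list alone 4 fell and 1 rose. DESeq2 called 4 of them (Cdk4, Cdk6, Cdc25b and Ccng1, 1 up and 3 down). With the 4 tissue scores the list was lower by camera (adjusted p = 0.0420, but 0.503 with an estimated correlation) and by fry (adjusted p = 0.0106). Of 31 proliferation genes 0 passed (median -0.25, list adjusted p = 0.418), the nearest being Cenpf (-0.38 ± 0.21, adjusted p = 0.293). With the 4 tissue scores the proliferation list was lower by camera (adjusted p = 2.71e-08, but 0.675 with an estimated correlation) and by fry (adjusted p = 0.0333), and Cenpf (-0.56, adjusted p = 0.00567), Plk1 (-0.83), Tpx2 (-0.60) and Cdc20 (-0.45) passed as lower. Without the lymphoid-rich libraries Mcm3 and Mcm6, named after their values were seen, passed as higher. In these 27 libraries, which were chosen by the lymphoid score, its mean was -1.04 in KO and -2.33 in WT. Among them the score thus went with genotype, and its part in these calls was not tested. With all libraries and no tissue score, 0 of the 31 passed by DESeq2, and by edgeR 0 had an unadjusted p under 0.05 and 0 were rhythmic in WT (18 unadjusted), with Cdk1 at a fitted peak of ZT 17.8 (0.56 ± 0.22, adjusted p = 0.232). Of the lymphoid markers 11 of 16 also had an unadjusted p under 0.05 for rhythm in WT.

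Of 16 immediate early genes, 16 interferon response genes, 5 genes for proteins that bind Pth mRNA and 4 cold-inducible genes, 0 passed by genotype in edgeR (1, 1, 1 and 0 unadjusted), and DESeq2 called 0, 0, 1 and 0. Their list adjusted p were 0.361, 0.652, 0.777 and 0.581, and their medians 0.14, 0.27, -0.02 and 0.05. Fos averaged 11.7 CPM in WT and 17.8 CPM in KO (0.49 ± 0.24, adjusted p = 0.238), and Dynll1, a gene for a protein of the Pth mRNA group, 46.6 and 40.1 CPM (-0.20 ± 0.07, adjusted p = 0.0645). The 12 E-box clock genes had a list adjusted p of 0.660, with a median (-0.05) and a mean (-0.02) opposite in sign to the test's direction, which was up.

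Markers of neighbouring tissues differed more between libraries than between genotypes. The mean log2 CPM of 16 lymphoid markers was -0.84 ± 2.67 in WT and 0.10 ± 2.00 in KO (SD, n = 21 and 18; p = 0.223, two-sided permutation test), and that of 14 thyroid follicle markers was 2.38 ± 2.42 and 1.66 ± 2.58 (p = 0.376). Of the 11 marker scores 0 passed the permutation test with 100000 resamples (adjusted p = 0.942 for each) and 0 had an unadjusted p under 0.05. Single markers passed by edgeR in 3 of the lists. In skeletal muscle Ttn rose (0.71 ± 0.20) and Myl1 (-0.41 ± 0.11) and Myh1 (-0.47 ± 0.14) fell, the thyroid C cell list held Gfra4 (-0.38 ± 0.11), which fell, and the nerve list held Ncmap, a myelin gene, which rose from 2.60 to 4.93 CPM (0.91 ± 0.16, adjusted p = 2.12e-04). Of these 5, Ncmap alone passed without the lymphoid-rich libraries. Myh1 also lost its call in 4 other alternatives and in 7 of the 39 fits that left out 1 library. Ttn lost it in 3 other alternatives and in 1 of those fits. As lists, thyroid follicle (adjusted p = 0.122), fibroblast matrix (0.122), skeletal muscle (0.415), adipose (0.629), endothelial (0.660), macrophage (0.660), blood (0.660), C cell (0.660), nerve (0.765) and airway epithelium markers (0.538) did not pass camera. Thyroid follicle markers passed as lower without 2 libraries of unusual composition (adjusted p = 0.0122) and in 7 of the 39 fits that left out 1 library. Fibroblast matrix markers passed as lower with the 4 tissue scores (adjusted p = 0.00485) and in 6 of those fits. Neither list passed with an estimated correlation there. In the blood, C cell, nerve and airway lists the median and the mean of the members had opposite signs. Of the thyroid follicle, lymphoid, adipose, blood, macrophage, endothelial, fibroblast and airway markers 0 passed by edgeR or DESeq2, and 0, 0, 1, 1, 0, 1, 1 and 0 had an unadjusted p under 0.05 by edgeR.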

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

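The test of which time the 3 samples with 2 times lie nearest to was chosen after the result was seen, and the counts over regrouped samples were planned. The rhythm of Cry1 (adjusted p = 2.42e-08) and the immunoglobulin segment Igkv3-12 (adjusted p = 0.0268) differed between genotypes by edgeR's interaction terms with Benjamini-Hochberg adjustment. Cry1 swung 3.32-fold from trough to peak in WT and 1.10-fold in KO. With genotype reassigned within times, 20 of 100 assignments, the real one included, gave 3 or more such genes, so chance cannot be excluded for the count itself, and the highest other assignment gave 234. In 7 assignments the count was over 3 times the real one, which points to a structure of the samples, and which one was not tested.

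Single samples stood apart from their group by Dixon's ratio in 12 of 124 combinations of a group of 4 or 5 samples and a measure (library total, marker scores and clock genes); chance gives about 1 in 20, and the measures are correlated. In WT ZT4, replicate 1 was the highest for Arntl (34.4 CPM against 26.9 to 27.1, ratio 0.972) and the lowest for Dbp (9.5 against 20.0 to 21.5 CPM, ratio 0.880), and replicate 4 had the lowest endothelial score (2.71 against 3.83 to 3.96, ratio 0.901). In WT ZT16, replicate 1 was the highest for Nr1d2 (172 against 51.0 to 77.0 CPM, ratio 0.785) and Dbp (24.9 against 12.0 to 14.9 CPM, ratio 0.776), replicate 5 the lowest for Bhlhe40 (6.38 against 9.08 to 10.1 CPM, ratio 0.719) and replicate 3 the highest for the fibroblast score (6.74 against 5.79 to 5.99, ratio 0.798). In WT ZT20, Hlf was highest in replicate 2 (2.67 against 0.760 to 1.05 CPM, ratio 0.847). In KO ZT20, the thyroid score was lowest in replicate 4 (-2.82 against 2.77 to 3.59, ratio 0.872), the fat score (4.11 against 1.48 to 1.72, ratio 0.910) and Bhlhe40 (11.5 against 6.16 to 6.78 CPM, ratio 0.885) were highest in replicate 2, and Nr1d2 was highest in replicate 1 (34.4 against 25.9 to 26.3 CPM, ratio 0.957).

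WT ZT16 replicates 4 and 5 and KO ZT16 replicate 1 had ZT16 in the title and ZT 20 in another label, and Arntl varied most in WT at ZT16 (7.96 to 32.3 CPM). Over the clock genes, 0 of these 3 samples lay nearer to the ZT20 than to the ZT16 mean of their genotype, but by as little as 0.362 against 0.365 in replicate 5. Of the 13 samples of those times with a single label only 9 lay nearer to their own time, so sampling at ZT16 and at ZT20 cannot be told apart this way. With these samples placed at ZT 20 or left out, 8 or 9 genes were rhythmic in KO against 14, and Arntl and Nr1d2 in KO lost their calls when placed at ZT 20. No biological explanation was tested.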

How the results depend on the processing

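The halved counts, the fit without 2 libraries and the fit without lymphoid-rich libraries were chosen after the data were seen. The genotype count (1435) became 2158 with 4 tissue scores and 454 without lymphoid-rich libraries, where fewer samples were tested and KO had none at ZT12; the cause of the former was not tested. The WT rhythm count (45) was 27 with the replicate block, 342 by DESeq2, 23 without 2 libraries, 25 without lymphoid-rich libraries and 21 with 17 samples of each genotype (median of 20 draws; 10 in KO, and WT had more in 18 of them); apart from fewer samples, the cause was not tested. The KO rhythm count (14) was 8 with 3 samples at ZT 20, 9 with them left out, 1 with 4 tissue scores, 7 with the replicate block, 85 by DESeq2, 8 with time as a factor and 2 without lymphoid-rich libraries; the cause was not tested. With the estimated correlation 1 gene list passed in place of 7. The estimates for the lists that lost their call ran from 0.183 (glycolysis) to 0.760 (ribosomal proteins), above the preset 0.01. At that preset value, genotypes reassigned within times gave a median of 9 lists. Without lymphoid-rich libraries 1 marker score passed in place of 0, the lymphoid score by which those libraries were chosen, so this test decides nothing. The counts of genes with a different rhythm, of clock contrasts and the Arntl fold change kept their side under the alternatives run. Leaving out 1 sample at a time gave 1125 to 1735 genes by genotype, 27 (without WT ZT12 replicate 3) to 63 rhythmic in WT, 7 (without KO ZT4 replicate 3) to 19 in KO (8 without KO ZT12 replicate 1, 9 without KO ZT8 replicate 1 or KO ZT16 replicate 1), 2 to 4 with a different rhythm, 38 to 47 clock contrasts, 5 to 9 lists, 0 to 0 marker scores and an Arntl log2 fold change of -0.35 to -0.18. Replicate numbers did not pair samples at all times: 8 of 17 same-number pairs correlated above 0.1 (median 0.0752, from -0.293 to 0.510, against -0.0442 for other pairs). At ZT0 same-number pairs lay at 0.190 to 0.376 and the others at 0.0139 or less, while at ZT16 same-number pairs lay at -0.293 to 0.0752. A pairing at single times stays open. Apart from the rhythm counts above, the block moved no count by over 1.5 times. Of 2404 alternative fits of 165 results of named genes, 2238 kept their side, 97 lost and 64 gained a call, and 5 uncalled values changed sign: Hlf 0.0211 without lymphoid-rich libraries, Per1 -0.0065 with the block, -0.0679 with no time term and -0.0241 without lymphoid-rich libraries, and Per3 0.0760 with 4 tissue scores (the cause was not tested). With 1 sample left out the log2 fold changes that changed sign ran from -0.0136 (without KO ZT0 replicate 2) to -0.0029 (without WT ZT8 replicate 2) for Per1 and from 0.0043 (without WT ZT4 replicate 2) to 0.0359 (without WT ZT8 replicate 2) for Per3, and Hlf reached 0.0337 (without WT ZT8 replicate 2). Depth limits the genes of low expression: 1 CPM is 38.1 to 68.9 counts in a library.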

Other observations

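Cpt1a and the 7 other rhythmic genes named beside it were chosen after their values were seen, as were the tests by position on the chromosomes and of the Trim relatives and the choice to leave out 2 or 12 libraries. The counts over regrouped samples and the correction by tissue scores were planned. Among other genes rhythmic in WT, Cpt1a, which serves mitochondrial fatty acid import, peaked at ZT 8.73 (peak to trough 1.74-fold, adjusted p = 0.00164 by edgeR with Benjamini-Hochberg adjustment) and Acsl1, which activates fatty acids, at ZT 3.51 (1.5-fold, adjusted p = 0.00982). Around the start of the night Lonrf1 (2.54-fold, adjusted p = 0.00619), Gadd45g (2.86-fold, adjusted p = 0.0340), Hif3a (2.94-fold, adjusted p = 0.0499) and Sox4 (1.56-fold, adjusted p = 0.0202) peaked, between ZT 12.4 and 13.3. In KO the fatty acid enzyme gene Eci2 (1.46-fold, peak ZT 7.41, adjusted p = 0.00315) and Fmo2 (2.34-fold, peak ZT 16.6, adjusted p = 0.0330) passed. Each of these 8 genes passed in 1 genotype alone, and the difference in rhythm between genotypes did not pass for any of them (adjusted p = 1.00 for each). Of the 13 fat markers 7 had an unadjusted p under 0.05 for rhythm in WT by edgeR, with Ucp1 past the test, and DESeq2 called Pparg and Ucp1. So had 11 of 16 lymphoid, 8 of 13 fibroblast matrix and 7 of 10 airway markers, with 0 past the test by edgeR. A change of tissue content with time stays open for Cpt1a and Acsl1, and for the collagen gene Col5a3.

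Regrouping the samples showed which counts chance could give. Of 100 assignments of genotype within times, real one included, 1 gave as many genotype calls as the real 1435 (highest other 230), and of 60 such assignments 1 gave as many clock contrasts as the real 41 (highest other 11). Of 100 shuffles of time within a genotype, real one included, 1 gave as many rhythmic genes in WT as the real 45 (highest other 18). In KO 2 gave as many as the real 14 (highest other 21). Such counts were rare under chance, but 100 or 60 regroupings cannot exclude it, and in KO a shuffle called more genes than the real times. Counts as high as the 7 gene lists were common under chance: 81 of 100 assignments gave as many, with a median of 9 and a highest other of 16.

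Oxidative phosphorylation genes were lower in KO after TMM scaling, with a list median of -0.14. The list call was lost by camera with an estimated correlation (adjusted p = 0.693). After the same scaling the median over all tested genes was 0.000977. Without TMM, KO minus WT of the fibroblast matrix score moved from -0.179 to -0.0957, and of the endothelial score from -0.0123 to 0.0707. This list was not fitted without scaling factors, so how far its median rests on them was not tested. Of 100 assignments 1, the real one, had a median as far from 0, and the highest other was 0.0984. Chance is thus unlikely for this median but not excluded, since the share is not corrected for looking at 28 lists. Thyroid, lymphoid, muscle and fat tissue as the whole cause is argued against by a median of -0.15 with their 4 scores as covariates. The scores of the other tissues were not used as covariates, so this does not speak for them. The 2 libraries of unusual composition as the cause are argued against by a median of -0.13 without them. Without the 12 lymphoid-rich libraries the list still passed camera (adjusted p = 2.63e-11) but not fry (adjusted p = 0.179) or with an estimated correlation (adjusted p = 0.728), and 2 of its 39 genes passed against 15, with fewer samples tested. A part played by other tissue stays open, as does a lower mitochondrial gene expression in KO glands, for which there are no independent samples.

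Genes changed at least 2-fold by genotype were most numerous on chromosome 7, with 28 of 1387 tested. The next highest counts were 14 of 852 on chromosome 3 and 14 of 963 on chromosome 6, where fewer genes were tested. Chromosome 2, with 1387 tested, had 7. Within 10 Mb of Arntl there were 11 of 164 tested, and 163 elsewhere (p = 4.04e-07, Fisher's exact test across genes, which are not independent). Over all 18661 genes tested there were 174. Of 127 spans of 20 Mb 1, the one that holds Arntl, had as many as 11 (the next highest had 8). By share the span of Arntl (5.98%, 11 of 184) came after 40000001 to 60000000 on chromosome 8 (7.35%, 5 of 68). Chromosome 7 also had 7 of 201 in 40000001 to 60000000 and 6 of 134 in 80000001 to 100000000, so its excess was not confined to the surroundings of Arntl. A candidate explanation is a linked strain haplotype, a stretch from another strain that travels with genotype, but both genotypes carried 2 floxed alleles, so a stretch linked to that allele would be shared, and whether the Cre transgene lies near is not given; an effect of the deletion on its neighbours was not tested and stays open. Of the 11, 6 lie in a Trim cluster with 11 tested genes (104218795 to 104507853), and outside it 5 of 153 changed 2-fold (p = 0.0126, Fisher's exact test), among them Stk33 (log2 fold change -1.21 ± 0.26) and Micalcl (1.28 ± 0.25). Strain haplotypes at many places stay open: 1 window of 5 Mb had an excess of called genes (80000001 to 85000000 on chromosome 7, 16 of 61 called), and the other regroupings had a median of 1 and a highest of 5. For Trim12a, 5.11 CPM in WT and 2 counts in KO, reads moved to paralogs are a candidate. The summed CPM of Trim12a and 9 relatives was 43.4 ± 7.86 in WT and 43.4 ± 6.10 in KO (SD), a ratio of 1.00. The difference was 0.0953 (95% Welch interval -4.44 to 4.63, below the 5.11 that Trim12a lost). In that sum Trim12c (20.5 to 28.3 CPM) and Trim34b (1.05 to 2.87) rose. Trim5 (1.10 to 0.11), Trim30d (1.13 to 0.104), Trim30b (0.0985 to 0.0126) and Trim34a (8.45 to 6.07) fell. If both genotypes were counted alike, sharing alone gives no difference unless their sequence differs, which was not tested. Separate changes of the relatives that cancel the loss of Trim12a stay open.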
